A study of Oryza sativa with 6 samples.

How the data were processed

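RNA was taken from leaves of rice (Oryza sativa) seedlings that were 3 weeks old and had been grown on half-strength MS medium, a defined plant culture medium, and libraries were made by Illumina protocols, per the labels' protocols. The series holds 3 libraries of the wild type ZH11, a japonica rice variety, and 3 libraries of DGP1-OE1, an overexpressor of DGP1. Groups and replicate numbers were read from the sample titles. All titles also carry the label Ck, which they do not explain. The labels do not say whether replicates were separate plants or pools, so the p-values measure the spread between these libraries, which may be technical.

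The deposited table gives FPKM, a fragment count scaled to transcript length and library size, made by the authors for 19696 rows. HISAT2 2.0 (an aligner), StringTie 1.3.0 (a transcript assembler and quantifier) and Bowtie 0.12.2 (an aligner) are named in the submitters' processing notes with no role or order. These notes also name the genome build mm8, which is a mouse build and does not go with the rice locus IDs in the table; the rice build and annotation are not given in the sources used here. Of the rows, 18804 carry a rice locus ID and 892 a NewGene ID. No row was 0 in all libraries, and the lowest row maximum was 0.169 FPKM. The ZH11 columns carry the names given in the sample descriptions. The overexpressor columns are called DGP1-OE with a number, where the descriptions say DGP1-OE1 with a number, and were taken as the same because the series has 1 overexpressor, with the number as the replicate.

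Sequencing depth is unknown, because the table holds no counts and low values showed no common step worth 1 read: in any pair of libraries, at most 3.7% of the genes under 0.5 FPKM in both shared 1 ratio within 0.02 log2 units. No counting interval or detection limit is therefore given, and a gene at 0 is described only as listed at 0. FPKM depends on the transcript models used and on the other genes of the library, so a few very abundant genes lower all others.

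A gene was tested when its FPKM was at least 1 in at least 3 of the 6 libraries, which left 18270 genes (17440 with a locus ID and 830 NewGene rows). Values were put on the log2(FPKM + 1) scale with no further scaling and fitted with limma 3.58.1 (R 4.3.3) as DGP1-OE1 minus ZH11, with empirical Bayes moderation and an intensity trend. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Every adjusted p of a gene in the text is from this limma fit unless another setting is named. Differences on this scale understate the change of low genes. The fit was tested on simulated data with the real means of the 18270 genes, their moderated spreads and normal noise. A set of 200 genes was changed, drawn only from genes with a mean above 3 on the log2(FPKM + 1) scale. The fit recovered 44.8% of those changed by 1 log2 unit, 98.5% of those changed by 2 units and 100% of those changed by 4 units. It made 16 false calls among 178, a larger share than the threshold of 0.05 aims at, and changes in lower genes were not tested. The real fit made 65 calls, so the p limit was looser in the simulation. The recovered shares may therefore be too high for the real data.

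The test, the filter, the alternatives and 40 gene lists were fixed before the data were examined. The lists (photosynthesis, chlorophyll metabolism, carbon and nitrogen metabolism, hormones, stress, markers of other tissues and the protein family of DGP1 among them) were search patterns on gene descriptions. The table pairs no ID with a name or description, and 0 of its 19696 IDs matched the RefSeq rice gene table used here. No list could therefore be filled, no gene is named, and the level of DGP1 itself in each library was not checked. The rule for named genes asked for a description, for the largest rises and falls among called genes whose groups did not overlap and whose mean reached 5 FPKM in the higher group. Without descriptions it was applied to IDs, and only the first 2 IDs in each direction are printed. The chromosome of a gene was read from the 2 digits after Os in its ID, which are the chromosome number in this naming system, and the order of genes from the running number. No coordinates were used.

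Called genes were counted per chromosome and among NewGene rows with Fisher's exact test (two-sided, 13 tests adjusted together), against the other tested rows. Pairs of called genes within 5 places in ID order were compared with 10000 random draws of as many tested genes. Library measures were compared by exact permutation tests, which with 3 against 3 libraries cannot go below 0.1. The other settings tried were a pseudocount of 0.1, no filter, a filter at 5 FPKM, equal totals, median-of-ratios and quantile scaling, no intensity trend, robust moderation, the replicate number as a block, a minimum difference of 1 log2 unit, and leaving out each library.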

Results

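The transcriptome of rice leaves was measured by RNA sequencing in an overexpressor of DGP1 and in its wild type, to ask how DGP1 bears on metabolism. DGP1 is a plant protein known from earlier work to hold down chlorophyll synthesis in rice glumes. The data comprised 3 libraries of the overexpressor DGP1-OE1 and 3 of the wild type ZH11, all from seedlings 3 weeks old. The deposited values were FPKM, with no counts, so the depth behind each value is unknown. FPKM summed over the listed rows to between 686327 and 752617 per library, with medians between 6.69 and 8.29 FPKM.

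By the median, libraries of the same genotype were only slightly more alike than libraries of different genotypes. Across the 18270 tested genes, which are not independent replicates, Pearson's r was computed on the log2(FPKM + 1) scale. It ranged from 0.913 to 0.951 within genotypes (median 0.9355) and from 0.893 to 0.942 between them (median 0.922). ZH11 replicate 2 correlated best with DGP1-OE1 replicate 2 (0.942), and ZH11 replicate 3 with DGP1-OE1 replicate 1 (0.937). The other libraries correlated best with a library of their own genotype. The first principal component held 33.4% of the variance and did not separate the genotypes. ZH11 replicates 1 and 3 and DGP1-OE1 replicate 3 lay on one side of it, at -37.1, -43.6 and -11.1. ZH11 replicate 2 and DGP1-OE1 replicates 1 and 2 lay on the other side, at 16.3, 11.9 and 63.7. On the second component, with 26.9% of the variance, the ZH11 libraries lay at -30.3, -33 and -9.45 and the DGP1-OE1 libraries at 20.4, -8.82 and 61.2, so that all ZH11 libraries lay below all DGP1-OE1 libraries, ZH11 replicate 3 and DGP1-OE1 replicate 2 by a narrow margin. The 10 most abundant rows took 17.7% ± 1.19 of all FPKM in DGP1-OE1 and 14.3% ± 0.513 in ZH11 (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest this design allows). The number of rows listed at 0 was 378, 161 and 372 in ZH11 and 56, 165 and 637 in DGP1-OE1 (exact permutation test, two-sided p = 1).

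**Figure D1:**
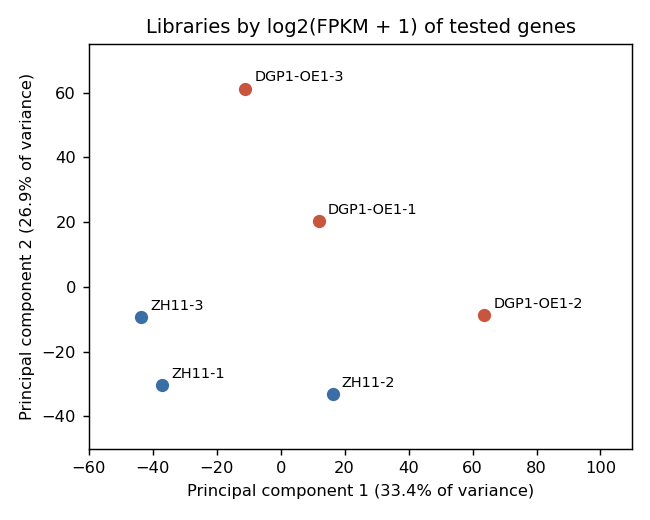
Position of the 6 libraries on the first and second principal components (axes in component scores, with the share of variance in percent) of log2(FPKM + 1) over the tested genes; blue points are ZH11, red points DGP1-OE1, and the number after the name is the replicate. Along the first component ZH11 replicate 2 sits at 16.3, between DGP1-OE1 replicates 1 (11.9) and 2 (63.7), and along the second component every ZH11 library lies below every DGP1-OE1 library, by the narrowest margin at -9.45 against -8.82.

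Overexpression of DGP1 went with higher expression of 29 genes and lower expression of 36 genes, out of 18270 tested. The ID of DGP1 is not known here, so any raised gene, the most abundant one included, may be DGP1 itself. The raised genes mostly had low listed values in the wild type. Their mean FPKM had a median of 0.397 in ZH11 and 21 in DGP1-OE1, 19 of the 29 had a ZH11 mean under 1 FPKM, and 9 were listed at 0 in all 3 ZH11 libraries. The lowered genes mostly had higher values there, with a median of 62.4 FPKM in ZH11 against 11.1 in DGP1-OE1. Of these 36 genes, 12 had a ZH11 mean of 100 FPKM or more, and 1 was listed at 0 in all 3 DGP1-OE1 libraries. Part of this contrast was set by the test. A gene near 0 in ZH11 could only be called higher, and a lowered gene needed a ZH11 level high enough to fall. The ZH11 levels of all tested genes were not set beside these.

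All 65 called genes differed by at least 1 log2 unit and none had overlapping groups of libraries, but the test could let little else through. At the p of the weakest call, a difference under 1 log2 unit could have passed for 66 of the 18270 genes, given their SEs. Among the called genes the median difference on the log2(FPKM + 1) scale was 3.15 for the raised genes and -2.51 for the lowered genes, with a median SE of 0.352. Without overlap, but not necessarily past the adjusted threshold, were 1228 higher and 1313 lower genes, 13.9% of those tested, where chance gives 10% for 3 against 3 libraries. An unadjusted p under 0.05 was reached by 1607 genes, or 8.8%. The median difference over all tested genes was -0.0096.

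The most abundant raised gene, a locus on chromosome 1, went from 64.3 ± 27.1 FPKM in ZH11 to 988 ± 234 FPKM in DGP1-OE1 (SD, n = 3 each), a 15.4-fold higher mean. Its log2 difference was 3.98 with an SE of 0.304 (limma, adjusted p = 0.000138). The most abundant lowered gene, a locus on chromosome 7, had 8550 ± 4350 FPKM in ZH11 and 366 ± 332 FPKM in DGP1-OE1, a mean 23.3 times as high in the wild type. Its log2 difference was -4.85 with an SE of 0.604 (limma, adjusted p = 0.0051). Without DGP1-OE1 replicate 3 the ratio of the means was 47.6 and the log2 difference -5.57, without DGP1-OE1 replicate 2 they were 17.2 and -4.16, and without ZH11 replicate 1 this gene was no longer called (limma, adjusted p = 0.0509). Robust moderation also ended its call (limma, adjusted p = 0.187). These 2 loci, and the ratios without single libraries here and below, were picked after their values were seen.

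The 2 loci with the largest rises in the fit of all 6 libraries were Os06g0685400 and Os07g0432201. Os06g0685400, on chromosome 6, was listed at 0 in all 3 ZH11 libraries and at 67, 43 and 81.8 FPKM in DGP1-OE1 replicates 1, 2 and 3, a log2 difference of 5.97 with an SE of 0.308 (limma, adjusted p = 1.44e-05). Os07g0432201 on chromosome 7 was listed at 0 in ZH11 replicates 1 and 2 and at 0.972 FPKM in replicate 3. In DGP1-OE1 it stood at 237, 16.8 and 85.2 FPKM, and its log2 difference was 5.83 with an SE of 0.731 (limma, adjusted p = 0.00518). The 2 loci with the largest falls were Os07g0147500 and Os01g0720500. Os07g0147500, also on chromosome 7, stood at 18.1, 303 and 448 FPKM in ZH11 replicates 1, 2 and 3, at 0.0411 FPKM in DGP1-OE1 replicate 1 and at 0 in the other two, a log2 difference of -7.09 with an SE of 0.898 (limma, adjusted p = 0.00555). Os01g0720500 on chromosome 1 fell from 426 ± 314 FPKM in ZH11 to 3.37 ± 2.12 FPKM in DGP1-OE1 (SD, n = 3 each), a mean 126 times as high in the wild type, and 75 times without ZH11 replicate 3. Its log2 difference was -6.45 with an SE of 0.508 (limma, adjusted p = 0.000138). The sizes of these differences depended most on the pseudocount where a group was at or near 0. With a pseudocount of 0.1 the log2 differences were 9.27 for Os06g0685400, 8.31 for Os07g0432201, then the third largest rise, -10.24 for Os07g0147500 and -6.87 for Os01g0720500. Sizes and the order within each pair also turned on single libraries. Without DGP1-OE1 replicate 2 the rises were 6.23 for Os06g0685400 and 6.84 for Os07g0432201, without ZH11 replicate 3 they were 5.97 and 6.16, and without ZH11 replicate 2 the log2 differences were -6.51 for Os07g0147500 and -7.01 for Os01g0720500. Without DGP1-OE1 replicate 1 the rise of Os07g0432201 was 4.96, the third largest instead of the second. The log2 difference of Os07g0147500 was -8.51 without ZH11 replicate 1 and -6.23 without ZH11 replicate 3. Robust moderation ended the calls of Os07g0432201 (adjusted p = 0.136) and Os07g0147500 (adjusted p = 0.234), and leaving out ZH11 replicate 1 ended that of Os07g0432201 (adjusted p = 0.0527).

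**Figure D2:**
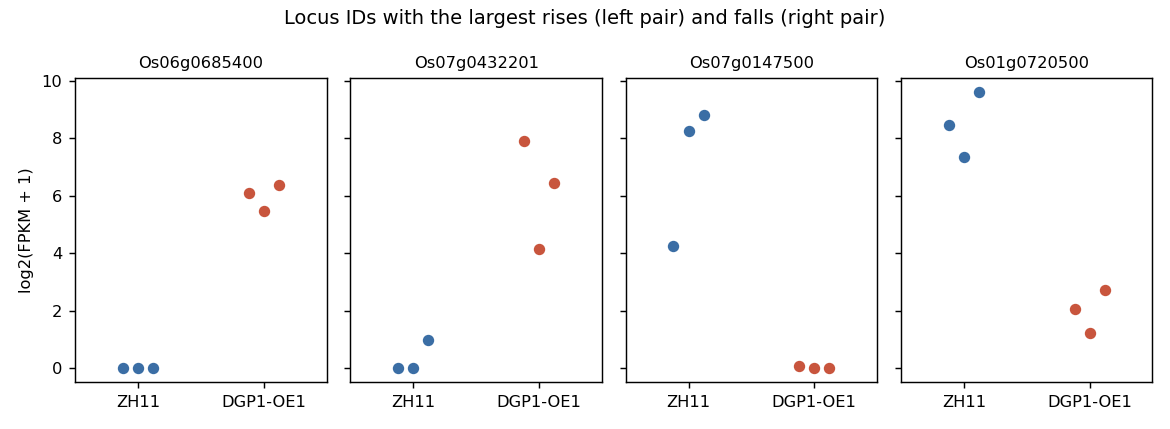
Expression on the log2(FPKM + 1) scale of the loci with the largest rises (Os06g0685400 and Os07g0432201) and falls (Os07g0147500 and Os01g0720500); each point is 1 library, in the order of replicates 1 to 3, with 3 ZH11 libraries in blue and 3 DGP1-OE1 libraries in red. In each panel all libraries of one genotype lie above all of the other, and ZH11 replicate 1 lies lowest of its group for Os07g0147500, at 18.1 FPKM.

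The called genes with a locus ID lay on all 12 chromosomes. Chromosome 12 held 8 of them among 966 tested genes (0.828%), 3 higher and 5 lower, against 0.329% among all other tested rows. Its odds ratio was 2.53, with a 95% interval of 1.04 to 5.34 (Fisher's exact test, p = 0.0208, adjusted p = 0.135 over 13 tests). The NewGene rows, which the sources used here do not define, held 8 called genes among 830 (0.964%). Among the 17440 genes with a locus ID 0.327% were called. That odds ratio was 2.97, with an interval of 1.22 to 6.28 (Fisher's exact test, p = 0.00897, adjusted p = 0.117). Neither excess passed the correction. Fisher's test takes genes as independent, but several called genes on chromosome 12 were neighbours. Its interval there may therefore be too narrow, and its excess is not separate from the pairs described below. Of the 8 NewGene rows 6 were higher and 2 lower, and of the 57 called genes with a locus ID 23 were higher and 34 lower (Fisher's exact test for the direction, p = 0.125).

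Called genes lay next to each other more often than random placement gives. Among the 57 called genes with a locus ID, 8 pairs stood within 5 places of each other in the order of tested genes, against a mean of 0.903 pairs in 10000 random draws (one-sided permutation p = 0.0001, the smallest the draws can give). The pairs comprised 13 genes on 5 chromosomes, 2, 6, 7, 11 and 12. Both members were lower in 5 pairs and higher in 1 pair, and in 2 pairs, which shared 1 raised gene on chromosome 12, they went opposite ways.

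**Figure D3:**
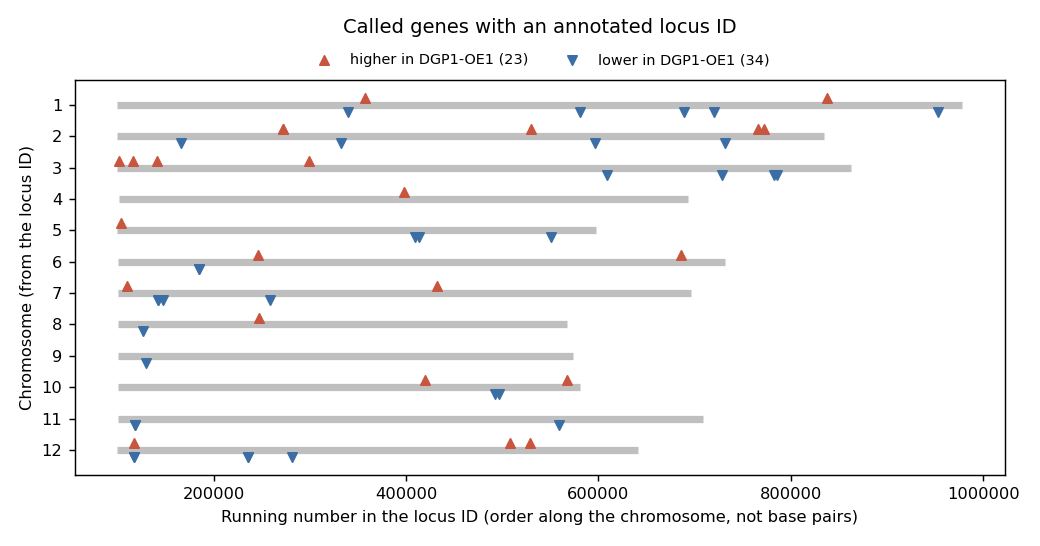
Called genes with a locus ID along the 12 chromosomes of rice; the x axis is the running number in the ID, which gives the order of genes and not base pairs, and grey bars span the tested genes. Red triangles mark the 23 genes higher and blue triangles the 34 genes lower in DGP1-OE1, and chromosome 12 carries 3 and 5 of them.

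Which genes passed depended on single libraries. Without ZH11 replicate 1 the test called 16 higher and 9 lower genes. Without DGP1-OE1 replicate 1 it called 18 and 12, and without ZH11 replicate 3 it called 27 and 11. The calls rose without ZH11 replicate 2, to 39 and 41, and without DGP1-OE1 replicate 2, to 35 and 42. Leaving out DGP1-OE1 replicate 3 gave 29 and 26. Fewer libraries also lower the power of a fit by themselves. Of the 65 called genes, 15 raised and 8 lowered ones were called in all 6 fits that left out 1 library. With median-of-ratios scaling the split was 32 higher and 24 lower genes instead of 29 and 36. Other settings moved it further. It was 34 and 14 without an intensity trend, 21 and 21 with a pseudocount of 0.1, and 130 and 139 with the replicate number as a block.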

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

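The counts of genes moved most with the replicate number as a block. They also depended on single libraries, the pseudocount and the intensity trend more than on the scaling. The 29 raised genes became 21 to 34, and the 36 lowered genes 14 to 38, under the other pseudocount, filters, scalings and moderations. The differences of the 4 printed loci kept their direction in every fit. These loci were chosen for large differences without overlap, so a reversal was hardly possible. Outside a range of 1.5 times lay the lowered genes with a pseudocount of 0.1 (21) and without an intensity trend (14). Leaving out each library in turn gave 16 to 39 raised genes and 9 to 42 lowered genes. A minimum difference of 1 log2 unit could not change the counts (29 and 36), since the smallest called difference was 1.25 log2 units in size. With the replicate number as a block 130 genes were raised and 139 lowered, and these held all 29 and all 36 genes called without it. The labels do not say that equal numbers share a plant, day or batch. Deviations from the group means of same-numbered libraries correlated at 0.016, 0.38 and 0.14 for replicates 1, 2 and 3. For different numbers the correlations ran from -0.28 to 0.21, the highest for ZH11 replicate 3 with DGP1-OE1 replicate 1. These values cannot settle whether equal numbers share a batch. The numbers were not taken as pairs because the labels do not pair them. The thresholds that follow were chosen after seeing the data. Genes near 0 in all DGP1-OE1 and present in all ZH11 libraries numbered 1 at limits of 0.5 and 5 FPKM, 4 with a limit of 1 for near 0, and 3 with a limit of 2 for present. The counts the other way were 10, 11 and 15. Pairs of neighbouring called genes numbered 8 within 5 places, 6 within 1 place and 13 within 20 places (one-sided permutation p = 0.0004 for the last). The cause of these differences was not tested. The other settings fixed in advance for the gene lists and for the family of DGP1 were not run, because no list could be filled. With depth unknown, it cannot be said which zeros and which missed calls come from low coverage. In simulated data, with changes only in genes of higher expression, 44.8% of changes of 1 log2 unit were called. The p limit was looser there than in the real fit, so this share may be too high. At the p of the weakest call in the real fit, a difference under 1 log2 unit could have passed for only 66 of the 18270 genes. Changes of that size will therefore mostly have been missed.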

Other observations

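All tests below were chosen after the main results were seen, and only the tests of independent gene loss, of neighbouring genes in other splits and of the lowest DGP1-OE1 library were set up before their own outcome was known. A set of 10 genes was listed under 0.5 FPKM in every ZH11 library and at 5 FPKM or more in every DGP1-OE1 library, and 1 gene showed the opposite. The 10 genes, all of them called, reached 6.69 to 81.8 FPKM in the DGP1-OE1 libraries. They comprised 4 NewGene rows and 6 genes with a locus ID on 5 chromosomes, and 7 were listed at 0 in all 3 ZH11 libraries.

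Shallower ZH11 libraries are one possible explanation for these 10 genes. Suppose that ZH11 libraries lost genes independently of each other and at 1 rate for all genes. Then 10 genes lost from all 3, out of 10114 present in all DGP1-OE1 libraries, would need about 2450 genes lost from exactly 1 ZH11 library. Only 11 were seen, which argues against loss at 1 rate and against nothing more. Loss at 1 rate takes genes whatever their level, which a shallow library would not be expected to do. Loss concentrated in a few genes would need fewer single losses, so this count cannot decide on it or on depth in general. The most such genes in either direction in any of the other 9 splits of the 6 libraries into 3 and 3 was 2, against 10 in the real split (1 of 10 splits as large), but 10 splits are too few for a share under 0.05. A candidate explanation is a genetic or epigenetic difference fixed between the DGP1-OE1 line and the ZH11 plants, and an effect of DGP1 itself is another. With 1 line per genotype these were not tested.

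The 65 called genes compare with at most 2 in the other 9 splits (1 of 10 splits as large), again too few splits for a share under 0.05. By unadjusted p under 0.05 the counts ran from 301 to 2098 over the 10 splits. Setting ZH11 replicates 1 and 3 and DGP1-OE1 replicate 3 against the rest gave 2098 genes, the genotype 1607, and ZH11 replicates 1 and 2 with DGP1-OE1 replicate 2 against the rest 1594, so by this count the genotype does not stand out. After adjustment the first of these splits called 1 gene and the last 0. The split with 2098 genes follows the sign of the first principal component, the axis of greatest variance, so its count restates that component.

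ZH11 replicate 2 was the lowest ZH11 library for 26 of the 36 lowered genes, and DGP1-OE1 replicate 2 the lowest DGP1-OE1 library for 21 of them. In ZH11 replicate 2 these genes stood at a median of 62.2% of the mean of ZH11 replicates 1 and 3, as 46% of overexpressor RNA in that library could give. Mixing would also bring genes that are listed near 0 in the other ZH11 libraries. The 11 genes under 0.5 FPKM in ZH11 replicates 1 and 3 and present in all DGP1-OE1 libraries had a median level of 0% of the DGP1-OE1 mean in ZH11 replicate 2, and the highest was 12.4%, which argues against mixing. A variation between libraries that runs through both genotypes stays open, since 21 of 36 lies between the bounds set for and against it.

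The 8 neighbouring pairs of called genes were not a matter of random placement (one-sided permutation p = 0.0001). Another explanation is neighbouring genes moving together in any comparison of these libraries. Equally long lists of the genes with the smallest p in the other 9 splits held at most 4 such pairs, which did not fall below the bound of 4 set beforehand, so this explanation stays open. Duplicated genes that share reads or regulation, and stretches of chromosome that differ between the line and the wild type, are not excluded either, and neither was tested because no sequence or name goes with the IDs.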
